A study of Mus musculus with 6 samples.

How the data were processed

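Total RNA of the Achilles tendon of C57BL/6 mice aged 18 weeks was used for 6 RNA-seq libraries, 3 from WT and 3 from Scx-Cre/Piezo1 GOF mice, and each library was placed in its group by the genotype in its label. Per the labels' protocols, RNA was isolated with a Direct-zol micro kit and libraries were made with the GenNext RamDA-seq kit and its mouse primers. Priming with this kit is not limited to poly(A) tails, so ribosomal precursor RNA and other RNA without a tail can take counts. The transcript Rn45s took 10.6 ± 2.81% of counts in WT and 10.5 ± 3.59% in Piezo1 GOF (SD, n = 3 each; two-sided exact permutation p = 1), and Lars2 took 4.70 ± 1.03% and 5.45 ± 2.44% (p = 0.8 by the same test).

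The deposited table holds estimated (expected) counts per gene, not scaled for depth or length, for 24411 genes, of which 6003 had a count of 0 in all 6 libraries. That the values are expected counts was read from the values themselves, of which 7.80% to 8.88% per library were not whole numbers, and from the submitters' processing notes. Per the submitters' processing notes, bcl2fastq, STAR, RSEM and edgeR were used by the authors, with no versions or roles given, and the genome build was mm10. The gene annotation and whether strand was used in counting are not given in the sources used here. Genes were identified by symbol, and 23334 symbols (95.6%) had a single match in GENCODE mouse release 21 on the same build, from which coordinates and identifiers were taken.

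Expected counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr of edgeR (minimum count 10), which left 13466 genes, and library sizes were scaled by the trimmed mean of M-values (TMM). The genotypes were compared with edgeR's quasi-likelihood F-test, two-sided and without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values were computed with edgeR's cpm function from the TMM-scaled library sizes (factors 0.897 to 1.10). Total counts per library lay between 8131527 and 17180856, and with 3 libraries per group a common dispersion of 0.113 sets the precision. The chain was tested on simulated counts for 13466 genes with the means, dispersions and library sizes of these data. Of these, 200 were changed for the recovery below, and a further list of 20 was raised 2-fold. It recovered 10% of 50 genes changed 2-fold, 70% of 50 changed 4-fold, 92% of 50 changed 8-fold and 98% of 50 changed 16-fold, with 14 calls among unchanged genes, and 0 calls when no change was simulated. Each gene was drawn independently, so the simulated counts held no variation shared between genes, such as that of muscle content. Replicates were compared before averaging, and the chi-square per degree of freedom between libraries of a genotype was 41.8 to 145, so no library was a copy of another.

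The gene lists numbered 37 with 638 entries, of which 620 entries were in the table, 5 of them under a synonym. They cover tendon and matrix genes, mechanical and growth factor signalling, metabolism, stress and inflammation, and markers of the cell types that a dissected tendon can hold. The mitochondrially encoded genes were not analysed here. The 34 lists with at least 3 tested members were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry, each with Benjamini-Hochberg adjustment over the lists. Members were also counted with the adjustment over the list alone. List scores are the mean log2 CPM of a list's tested members in a library. Genes were named by a rule: Piezo1 and Scx, up to 10 genes per direction among those past the threshold with a mean CPM of at least 5 and no overlap between the groups (leaving out predicted genes and mitochondrial rRNAs), list members past 0.05 over all genes, and up to 4 members with the smallest p for each list that passed. The last part also covered, in any case, the tendon transcription factors, tenocyte markers, fibrillar collagens, proteoglycans, collagen processing, YAP/TAZ targets and mechanosensitive channels, and the rule gave 83 genes, some of which are not reported here. Other list members, such as Tnmd, Vcan, Timp2, Col8a2, Frzb, Dkk3, Itga11, Camk4, Rgs5, Chodl and Sox9, and Bop1 outside the lists, were chosen after their values were seen. Shares of counts were compared with two-sided exact permutation tests, whose smallest p for 3 against 3 is 0.1.

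The alternatives were other scaling factors, other filters, DESeq2, the exact test of edgeR, limma voom with sample quality weights, the replicate number as a block, leaving out each library in turn, the muscle score as a covariate, removal of the muscle and erythroid lists, and other thresholds. Removal of Rn45s and Lars2, a robust prior and list counts without each library were added after seeing the data. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.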

Results

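Transcripts of the Achilles tendon were measured in 6 libraries from C57BL/6 mice aged 18 weeks. In 3 libraries the genotype was wild type (WT). In the other 3 it combined Scx-Cre, a Cre recombinase driven by sequence of the tendon transcription factor gene Scx, with a gain-of-function (GOF) allele of Piezo1, a mechanically gated cation channel. The libraries are named by genotype and replicate number. Libraries were made from total RNA with the RamDA-seq kit, whose priming of reverse transcription is not limited to poly(A) tails. Total counts were 8519513, 17180856 and 9869028 in WT replicates 1 to 3 and 8131527, 9061268 and 12631659 in Piezo1 GOF replicates 1 to 3, and between 15595 and 16594 genes had at least 1 count. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The comparison asks how the tendon transcriptome of the mutant mice differed from that of WT mice. Fold changes are Piezo1 GOF over WT on the log2 scale with their standard errors (SE), levels are CPM (counts scaled to a common library size) as mean ± SD with n = 3 per genotype, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

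The mutated gene itself differed little in transcript level between the genotypes, while the gene that drives the Cre was higher in the mutant. Piezo1 was at 121 ± 21.1 CPM (SD, n = 3) in WT and 153 ± 24.7 CPM in Piezo1 GOF, with overlapping groups and a log2 fold change of 0.34 ± 0.23 (SE; edgeR adjusted p = 0.442). A gain-of-function allele need not change the amount of transcript, so this value does not check the labels. Piezo1 (ENSMUSG00000014444.17) lies on the minus strand of chromosome 8 at 122481698 to 122551329 of the mm10 build. Scx, the tendon transcription factor gene, was at 17.2, 14.2 and 15.95 CPM in the WT libraries and at 77.9, 60.2 and 45.1 CPM in the Piezo1 GOF libraries. Its log2 fold change of 1.95 ± 0.25 missed the threshold over all genes by edgeR (adjusted p = 0.0572), and without WT replicate 1 it passed (adjusted p = 0.0343). Scx (ENSMUSG00000034161.8; chromosome 15, plus strand, 76457452 to 76459458) lies within the span of Bop1, a ribosome biogenesis gene on the minus strand at 76452989 to 76477277. Bop1, looked at after the Scx values were seen, was at 36.2 ± 9.15 CPM in WT and 319 ± 266 CPM in Piezo1 GOF (log2 fold change 3.14 ± 0.56; edgeR adjusted p = 0.0621), with 624 CPM in Piezo1 GOF replicate 1 and 141 and 191 CPM in replicates 2 and 3. The labels do not say whether strand was used in counting, so reads of Scx and Bop1 may be shared between the pair, and the Scx value is uncertain for that reason. The 8 other tested genes within 100 kb of Bop1 had a median log2 fold change of -0.20, between -1.11 for Hgh1 and 0.25 for Dgat1.

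**Figure D1:**
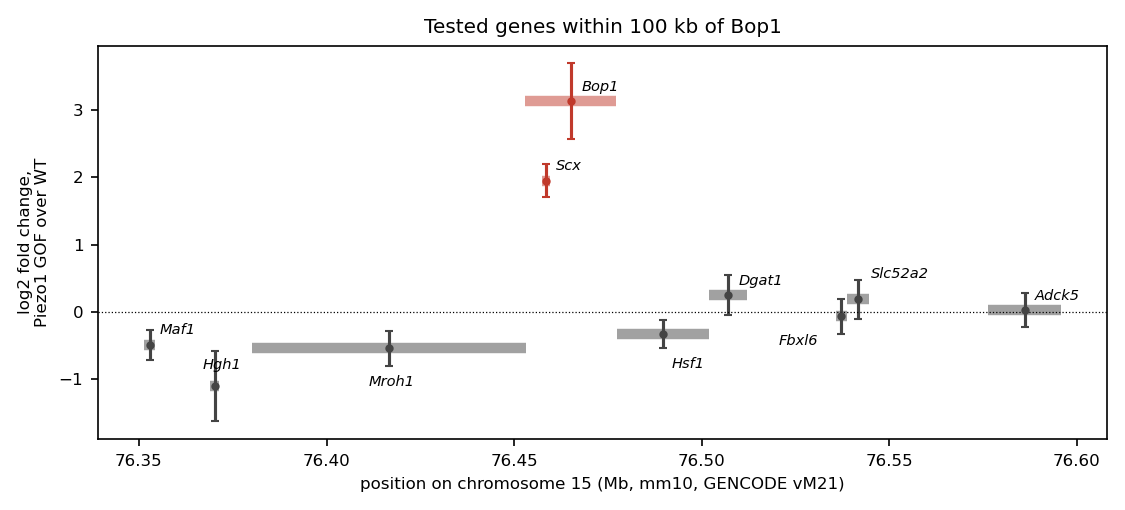
Log2 fold change of Piezo1 GOF over WT (vertical axis) of the tested genes within 100 kb of Bop1 against their position on chromosome 15 in Mb (horizontal axis, mm10). Thick bars mark the span of each gene, points the fold change and thin bars its SE from 3 libraries per genotype; Bop1 (3.14) and Scx (1.95), in red, lie above the other 8 genes (-1.11 to 0.25).

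Across all genes, Wif1 and Lyz1 rose in the Piezo1 GOF tendons and no gene fell past the threshold. Wif1, a secreted inhibitor of Wnt ligands, rose 6.03-fold from 15.5 ± 3.74 to 93.7 ± 19.2 CPM (log2 fold change 2.59 ± 0.27; edgeR adjusted p = 0.0431). Lyz1, which encodes a lysozyme, rose 4.82-fold from 7.96 ± 1.86 to 38.3 ± 2.96 CPM (log2 fold change 2.27 ± 0.24; edgeR adjusted p = 0.0431). All 3 mutant libraries lay above all 3 WT libraries for both genes, yet both calls held without WT replicate 1 (edgeR adjusted p = 0.0226) and were lost without any 1 of the other 5 libraries (0.0832 to 0.188). Wif1 (ENSMUSG00000020218.11) spans 121033960 to 121100650 and Lyz1 (ENSMUSG00000069515.6) 117287797 to 117292868 of chromosome 10. Lyz1 is a near-identical neighbour of Lyz2, the lysozyme gene of macrophages, which was at 95.1 ± 12.4 CPM in WT and 315 ± 20.7 CPM in Piezo1 GOF, so its value may hold Lyz2 reads and is uncertain.

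Of 13466 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called these 2 higher and 0 lower. At an unadjusted p under 0.05 it gave 1373 higher and 1291 lower. DESeq2, with its own filter and size factors, tested 14754 genes and called 511 higher and 371 lower. On the same 13466 genes, edgeR's exact test called 452 and 237, and limma voom with sample quality weights 97 and 19. The groups did not overlap for 3453 genes, or 25.6%, of which 1827 were higher and 1626 lower, against the 10% that chance gives for 3 against 3. The first principal component of the libraries held 47.7% of the variance and ordered all 6 libraries, within each genotype too, from the highest to the lowest share of skeletal muscle markers, so it separates the genotypes and follows muscle content alike. The count rose to 228 genes, 182 higher and 46 lower, without WT replicate 1, and was 0 without any 1 of the other 5 libraries. In the self-test on simulated counts the same fit recovered 10% of genes changed 2-fold, 70% of those changed 4-fold and 92% of those changed 8-fold. Simulated genes varied independently, without shared variation such as that of muscle content, so these rates need not hold for the real counts.

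By camera with a preset correlation, the matrix, tenocyte, cartilage, bone and macrophage groups were higher in Piezo1 GOF and muscle and oxidative phosphorylation genes lower. All groups were fixed before the data were examined. Of 34 lists with at least 3 tested members, 16 rose and 3 fell by camera with a preset correlation of 0.01, and 0 passed with an estimated correlation. Among the lists that passed, the estimated correlation ran from 0.089 (TGF-beta pathway) to 0.78 (fibrillar collagens), far above the preset. Other splits of the 6 libraries into 3 and 3, which mix the genotypes, called 7 to 20 lists. These splits hold the genotypes in unequal numbers on each side, so part of a genotype difference can remain in them. They are therefore no measure of chance alone. A count of 19 lists by itself does not set the genotypes apart. Apart from Wif1, no list member passed over all genes, so the counts of members below are those adjusted over the list alone, by the same edgeR test. Calls by other tools are over all genes. When a library was left out, the count filter was applied anew, so the number of tested members can differ there. The share of counts from skeletal muscle markers, given with that group, was lower in all 3 mutant libraries and so moved with every group described. Several lists share members, and 10 of the 12 tenocyte markers and 6 of the 15 proteoglycans also stand in another list.

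Genes of the differentiated tenocyte and of its collagen matrix were higher in the mutant. Of 12 tenocyte markers, 11 rose and 0 fell, with a median log2 fold change of 1.62 (camera adjusted p = 2.36e-05; adjusted p = 0.452 with an estimated correlation). Decorin (Dcn), a small proteoglycan that binds collagen fibrils, was at 2025 ± 750.3 CPM in WT and 10562 ± 5172 CPM in Piezo1 GOF, a log2 fold change of 2.38 ± 0.57. Keratocan (Kera) rose by 2.56 ± 0.71, the cartilage oligomeric matrix protein gene Comp by 2.03 ± 0.56, Cilp2 by 1.74 ± 0.64 and tenomodulin (Tnmd), a membrane protein of mature tenocytes, by 1.496 ± 0.58. The tenocyte marker Chodl was the exception at -0.79 ± 0.41. All 11 fibrillar collagens had positive fold changes, with a median of 1.09 (camera adjusted p = 3.17e-04; adjusted p = 0.452 with an estimated correlation). None of the 11 passed by edgeR with the adjustment over this list, where 5 had an unadjusted p under 0.05, while DESeq2 called 1, the exact test 0 and voom 0. Col1a1, Col1a2 and Col11a1 stand in both lists and passed only among the tenocyte markers, so their calls depend on the list over which p is adjusted, as do those of Col12a1, Thbs4 and Cilp2. Col1a2, a chain of type I collagen, was at 1941 ± 1647 CPM in WT and 9491 ± 3739 CPM in Piezo1 GOF (2.29 ± 0.91). Col5a2 had a log2 fold change of 1.34 ± 0.46, Col2a1 of 1.69 ± 0.69 and Col11a1 of 1.09 ± 0.47. The spread of these genes within WT was wide, and the mean log2 CPM of the fibrillar collagens was 7.22, 4.77 and 7.04 in WT replicates 1 to 3 and 7.59, 7.96 and 7.88 in Piezo1 GOF. Skeletal muscle markers took 9.49%, 17.2% and 14.7% of counts in WT replicates 1 to 3 and 7.96%, 3.01% and 7.30% in Piezo1 GOF. The count of 11 tenocyte markers fell to 7 without WT replicate 2, 5 without WT replicate 3, and 2, 1 and 0 without Piezo1 GOF replicates 1, 2 and 3, while 3 fibrillar collagens passed without WT replicate 1, and camera called both lists each time. The median of the fibrillar collagens was 0.66 without WT replicate 2.

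Proteoglycans and the enzymes that modify and crosslink collagen were higher as well. Of 15 proteoglycans, 10 rose and 0 fell, with a median log2 fold change of 1.99 (camera adjusted p = 7.10e-06; adjusted p = 0.448 with an estimated correlation). Aggrecan (Acan), the large proteoglycan of cartilage, rose from 12.9 ± 6.81 to 56.0 ± 9.42 CPM (2.12 ± 0.36). Lubricin (Prg4) rose by 2.34 ± 0.47, osteomodulin (Omd) by 3.43 ± 0.69 and versican (Vcan) by 2.39 ± 0.59. Biglycan (Bgn, 0.97 ± 0.50) and lumican (Lum, 0.72 ± 0.68) did not pass. Of 25 genes of collagen processing and crosslinking, 12 rose and 0 fell, with a median of 0.85 (camera adjusted p = 5.28e-08; adjusted p = 0.448 with an estimated correlation). Among them the lysyl hydroxylase Plod2 rose from 12.9 ± 0.931 to 54.8 ± 18.6 CPM (2.09 ± 0.29). Pcolce2, an enhancer of procollagen cleavage, rose by 2.62 ± 0.45, the prolyl hydroxylase subunit P4ha1 by 1.90 ± 0.42 and lysyl oxidase (Lox) by 1.70 ± 0.38. Without WT replicate 3, 6 proteoglycans and 2 processing genes passed, and without Piezo1 GOF replicate 2, 6 processing genes did and the proteoglycan median was 1.27.

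Among the other matrix groups, the 26 matrix glycoproteins and elastic fibre genes had a median log2 fold change of 0.59, and 4 rose while 0 fell (camera adjusted p = 3.24e-04; adjusted p = 0.452 with an estimated correlation). The 4 were the thrombospondins Thbs2 (1.34 ± 0.32) and Thbs3 (0.94 ± 0.24), fibulin-1 (Fbln1, 1.14 ± 0.30) and Comp. Of 18 matrix proteases and inhibitors, 5 rose and 2 fell, with a median of 0.53 (camera adjusted p = 0.0302; adjusted p = 0.452 with an estimated correlation). The aggrecanase Adamts5 rose from 59.1 ± 16.1 to 168 ± 2.33 CPM (1.51 ± 0.25), stromelysin-1 (Mmp3) by 3.63 ± 0.99, and the metalloproteinase inhibitors Timp1 by 2.08 ± 0.54, Timp2 by 1.33 ± 0.41 and Timp3 by 1.24 ± 0.38. Mmp11 (-1.16 ± 0.30) and Adamts1 (-0.99 ± 0.33) fell. The 13 other collagens did not pass as a list (camera adjusted p = 0.127), but did without WT replicate 1 (0.0251) or WT replicate 3 (0.0210), and 1 of them, Col8a2, rose (1.96 ± 0.48), a call lost without WT replicate 3 or Piezo1 GOF replicates 1 or 2. The glycoprotein count was 8 without WT replicate 1, 2 without WT replicate 2 and 0 without WT replicate 3 or any 1 mutant library, with a median of 0.36 without WT replicate 2. The protease median was 0.82 and 0.24 without WT replicates 1 and 2 and 0.32 and 0.26 without Piezo1 GOF replicates 1 and 3. For the proteases, 1 rose without WT replicate 2, WT replicate 3 or Piezo1 GOF replicate 3 and 3 without Piezo1 GOF replicate 2. Both lower calls were lost without WT replicate 2 or Piezo1 GOF replicates 2 or 3 and 1 of them without WT replicate 3 or Piezo1 GOF replicate 1, and the camera call was lost without WT replicate 2 (adjusted p = 0.0725), Piezo1 GOF replicate 1 (0.0543) or Piezo1 GOF replicate 3 (0.154).

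Tested markers of cartilage and bone were higher as sets in Piezo1 GOF. Of 13 cartilage markers, 5 rose and 0 fell, with a median log2 fold change of 1.28 (camera adjusted p = 3.17e-04; adjusted p = 0.448 with an estimated correlation). They were Acan, the link protein gene Hapln1 (3.11 ± 0.64), chondroadherin (Chad, 2.76 ± 0.81), the chondrogenic factor Sox5 (1.21 ± 0.36) and Ucma (2.11 ± 0.71). Chad went from 2069 ± 1551 to 13967 ± 6875 CPM. Sox9, the master regulator of chondrocytes, had a log2 fold change of 1.28 ± 0.48 and did not pass. Of the 13, 11 had positive and 2 negative values, the latter Sox6 (-0.47 ± 0.22) and Cytl1 (-0.11 ± 1.11). These 13 were tested of 18 cartilage markers, and the others, such as Col9a1 and Matn1, had too few counts. Of 7 bone markers, 5 rose and 0 fell, with a median of 1.48 (camera adjusted p = 3.17e-04; adjusted p = 0.448 with an estimated correlation). Osteopontin (Spp1) rose from 132 ± 74.8 to 1166 ± 294.6 CPM (3.14 ± 0.51) and bone sialoprotein (Ibsp) from 89.2 ± 80.9 to 1022 ± 656 CPM (3.52 ± 0.81). Alkaline phosphatase (Alpl) rose by 1.48 ± 0.26, the osteoblast factor Runx2 by 0.84 ± 0.25 and Sp7, at 0.324 CPM in WT and 1.65 CPM in Piezo1 GOF, by 2.37 ± 0.72. Of the 7, 6 had positive values and 1, Phex, a negative one (-1.85 ± 1.39). These 7 were tested of 12 bone markers, and the others, such as Bglap, Dmp1 and Sost, had too few counts. The number of cartilage markers past the test was 3 without WT replicate 2 and 2 without WT replicate 3 or Piezo1 GOF replicate 2, and that of bone markers lay between 4 and 6. The count filter was applied anew without each library, so 8 or 10 bone markers were tested there, against 7 with all 6 libraries. The bone median then lay between 1.76 and 2.15, so neither its change nor the bone counts reflect the library left out alone. The cartilage median was 2.005 without WT replicate 1.

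Macrophage markers formed the group with the smallest camera p. Of 15, 14 rose and 0 fell, with a median log2 fold change of 1.70 (camera adjusted p = 1.16e-14; adjusted p = 0.448 with an estimated correlation). The list also passed fry, which tests the direction of the set on its own (adjusted p = 0.0362), and 13 or 14 members passed whichever library was left out. The cathepsin gene Ctss rose from 9.88 ± 3.88 to 44.4 ± 9.48 CPM (2.18 ± 0.32), the complement gene C1qb from 12.3 ± 3.38 to 40.8 ± 2.72 CPM (1.74 ± 0.25) and the lipopolysaccharide co-receptor Cd14 from 7.24 ± 0.346 to 24.1 ± 6.19 CPM (1.74 ± 0.26). Lyz2 (1.73 ± 0.23), the mannose receptor Mrc1 (1.51 ± 0.23) and the colony-stimulating factor receptor Csf1r (1.33 ± 0.36) rose, and Cd163 did not pass (0.42 ± 0.30). Among 11 inflammatory mediators, 2 rose and 0 fell, with a median of 1.53 (camera adjusted p = 0.00141; adjusted p = 0.450 with an estimated correlation). The monocyte chemokine Ccl2 rose from 1.39 ± 0.845 to 10.6 ± 7.67 CPM (2.96 ± 0.63) and the nitric oxide synthase Nos2 by 1.53 ± 0.42, while Il33 (1.86 ± 0.63) and Ccl7 (1.94 ± 0.68) did not pass. The mediator count was 6 of 13 tested without WT replicate 1 or Piezo1 GOF replicate 1, 1 of 11 without Piezo1 GOF replicate 2 and 0 without WT replicate 2 or Piezo1 GOF replicate 3. Of 10 neutrophil markers only 2 had enough counts to be tested, too few for camera. Both rose with the adjustment over these 2 alone, namely Lcn2 (3.11 ± 0.47) and S100a8 (4.39 ± 0.72). The others, such as S100a9 and Mpo, were not tested, so these 2 genes do not speak for the list. No lymphocyte marker had enough counts to be tested, and the 14 interferon response genes did not pass (median 0.34; camera adjusted p = 0.0626), except without WT replicate 1 (0.0191; median 0.55) or Piezo1 GOF replicate 2 (0.00207; median 0.66).

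Skeletal muscle markers were lower in the mutant as a set. Their share of all counts was 13.8 ± 3.91% in WT and 6.09 ± 2.69% in Piezo1 GOF (n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The share of tenocyte markers was 1.07 ± 0.6004% in WT and 4.02 ± 1.502% in Piezo1 GOF (n = 3 each; two-sided exact permutation p = 0.1). The 27 muscle markers fell with a median log2 fold change of -1.04 (camera adjusted p = 2.36e-05; adjusted p = 0.452 with an estimated correlation), and 26 of the 27 had negative values. None passed alone by edgeR, where 7 had an unadjusted p under 0.05, while DESeq2 called 9 lower, the exact test 4 and voom 0. The members with the smallest p were troponin C1 (Tnnc1, -1.89 ± 0.45), the slow myosin heavy chain Myh7 (-2.16 ± 0.61), Tnni1 (-1.42 ± 0.40) and Tnnt1 (-1.52 ± 0.52). Myh7 was at 10642 ± 4622 CPM in WT and 2385 ± 1234 CPM in Piezo1 GOF. The 22 nuclear-encoded genes of oxidative phosphorylation fell with a median of -0.69, and all 22 had negative values (camera adjusted p = 5.79e-07; adjusted p = 0.452 with an estimated correlation). None passed alone by edgeR, with 4 at an unadjusted p under 0.05, and DESeq2, the exact test and voom each called 0. Examples were Ndufb5 (-0.83 ± 0.34), Cox5a (-0.83 ± 0.36), Uqcrc2 (-0.76 ± 0.33) and cytochrome c (Cycs, -0.68 ± 0.30). The 19 glycolysis and hypoxia genes did not pass (median -0.38; camera adjusted p = 0.127), except without Piezo1 GOF replicate 1 (0.0455), and 1 of them, Pfkp, rose (1.02 ± 0.23) with a call that was lost without WT replicates 2 or 3 or Piezo1 GOF replicates 2 or 3. Without Piezo1 GOF replicate 1, 8 muscle markers and 16 oxidative phosphorylation genes passed, and without WT replicate 1, 3 muscle markers did. The muscle median was -0.67 without WT replicate 2 and -0.60 without Piezo1 GOF replicate 2, and that of oxidative phosphorylation was -0.42 and that of glycolysis and hypoxia -0.23 without the latter.

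**Figure D2:**
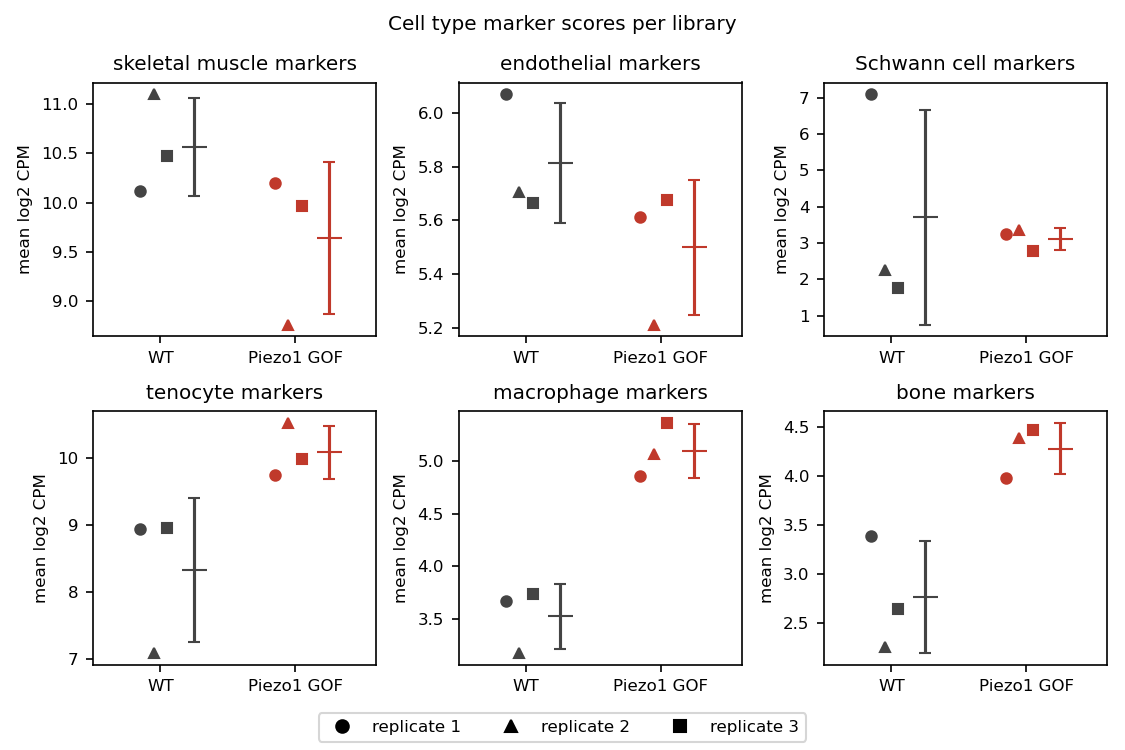
Mean log2 CPM (vertical axes) of 6 cell type marker lists in each library, with WT in grey and Piezo1 GOF in red; symbols mark replicates 1 to 3 and the bars show the mean ± SD of 3 libraries. Tenocyte, macrophage and bone scores separate the genotypes, muscle scores overlap, and WT replicate 1 stands at 7.10 for Schwann cell markers against 1.77 to 3.35 in the other 5 libraries.

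Markers of other cell types in a dissected tendon went in both directions. Of 14 sheath and interstitial fibroblast markers, 5 rose and 0 fell, with a median log2 fold change of 0.70 (camera adjusted p = 6.00e-05; adjusted p = 0.448 with an estimated correlation). They were Clec3b (2.15 ± 0.34), Prg4, Ly6a (1.12 ± 0.29), Dpp4 (0.96 ± 0.30) and Sema3c (0.75 ± 0.24). The 15 adipocyte markers rose as a set with a median of 0.998 (camera adjusted p = 0.0102; adjusted p = 0.452 with an estimated correlation). Among them leptin (Lep) rose from 19.8 ± 8.24 to 112 ± 51.2 CPM (2.50 ± 0.44), while Adipoq (1.47 ± 0.49), Scd1 (1.73 ± 0.62) and Plin1 (1.26 ± 0.52) did not pass. Of the 15, 11 had positive and 4 negative values, and the latter were Lpl, at 1212 ± 407 CPM in WT and 674 ± 143 CPM in Piezo1 GOF (-0.85 ± 0.36), Car3 (-0.60 ± 0.47), Pnpla2 (-0.63 ± 0.36) and Plin4 (-0.32 ± 0.45), none of which passed. The 15 endothelial markers fell with a median of -0.41 (camera adjusted p = 0.0316; adjusted p = 0.452 with an estimated correlation). None of them passed alone by edgeR, where 5 had an unadjusted p under 0.05, and DESeq2, the exact test and voom each called 0. Flt1 (-1.04 ± 0.37), Vwf (-1.38 ± 0.55) and Esam (-0.59 ± 0.24) had negative values and Erg a positive one (0.88 ± 0.26). Mural cell markers did not pass as a set (median -0.88; camera adjusted p = 0.0578), though the pericyte genes Rgs5 (-0.995 ± 0.30), Abcc9 (-1.07 ± 0.32) and Kcnj8 (-0.71 ± 0.22) fell and Ndufa4l2 rose (2.24 ± 0.36). The mural median was -0.16 without WT replicate 1 (camera adjusted p = 0.627), while the list passed without WT replicate 2 (0.0154), WT replicate 3 (0.00617) or Piezo1 GOF replicate 3 (0.0282), and 7 members fell without WT replicate 3 and 0 without any 1 mutant library. Erythroid (camera adjusted p = 0.0836), keratinocyte (0.485) and Schwann cell markers (0.414) did not pass, although the erythroid list did without WT replicate 1 (0.0323), WT replicate 2 (0.0412) or Piezo1 GOF replicate 2 (0.00208). WT replicate 1 held myelin transcripts, and its Schwann cell score, the mean log2 CPM of 12 markers, was 7.10 against 1.77 to 3.35 in the other 5 libraries. Without WT replicate 1 the median log2 fold change of the Schwann cell markers went from -2.59 to 1.36 and 4 members rose (camera adjusted p = 0.00150), while without WT replicate 2 or WT replicate 3 the list fell (0.0334 and 0.00879). The sheath count was 2 without WT replicate 2 or Piezo1 GOF replicates 2 or 3 and 3 without Piezo1 GOF replicate 1, and 6 adipocyte markers passed without WT replicate 1 and 5 without Piezo1 GOF replicate 1. The adipocyte call was lost without WT replicate 3 (camera adjusted p = 0.073) or Piezo1 GOF replicate 3 (0.145; median 0.54), and the endothelial call without WT replicate 1 (0.188; median -0.22) or Piezo1 GOF replicate 2 (0.113).

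Genes of growth factor signalling moved in both directions. Of 17 TGF-beta pathway genes, 3 rose and 1 fell, with a median log2 fold change of 0.41 (camera adjusted p = 0.00430; adjusted p = 0.448 with an estimated correlation). The ligand Tgfb1 rose from 15.3 ± 4.38 to 43.9 ± 12.1 CPM (1.52 ± 0.30), the induced matrix gene Tgfbi by 1.13 ± 0.25 and the signal transducer Smad3 by 0.85 ± 0.25. Of 19 BMP and GDF pathway genes, 4 rose and 0 fell, with a median of 0.74 (camera adjusted p = 0.0350; adjusted p = 0.452 with an estimated correlation). They were the joint and tendon growth factor Gdf5, from 2.10 ± 0.766 to 17.4 ± 8.65 CPM (3.07 ± 0.49), its receptor Bmpr1b (1.42 ± 0.28), Bmp2 (1.17 ± 0.34) and Id2 (1.80 ± 0.54). Of 16 Wnt signalling genes, 3 rose and 0 fell, with a median of 0.53 (camera adjusted p = 0.00676; adjusted p = 0.450 with an estimated correlation). They were Wif1, Frzb (2.99 ± 0.70) and Dkk3 (1.84 ± 0.47), in a list that holds many secreted antagonists and modulators. The 17 genes of the unfolded protein response had a median of 0.43 (camera adjusted p = 0.00234; adjusted p = 0.452 with an estimated correlation). None passed alone by edgeR, where 5 had an unadjusted p under 0.05, and DESeq2, the exact test and voom each called 0. The endoplasmic reticulum genes Creld2 (0.92 ± 0.26), Manf (0.94 ± 0.28), Pdia3 (0.66 ± 0.25) and Xbp1 (0.51 ± 0.20) led it. IGF and FGF signalling did not pass (camera adjusted p = 0.0515), with Igfbp6 higher (1.97 ± 0.46) and Fgf1 lower (-0.95 ± 0.24). It passed without any 1 WT library (0.0169 to 0.0467) or Piezo1 GOF replicate 3 (0.0152), and the calls of both genes were lost without WT replicates 2 or 3 or Piezo1 GOF replicates 2 or 3, while 6 members rose without WT replicate 1. Without WT replicate 3 the number that rose was 1 for TGF-beta, 2 for BMP and GDF and 1 for Wnt, and without WT replicate 1 it was 6 for Wnt. The Wnt median was 1.37 without WT replicate 1, 0.20 without WT replicate 2, and 0.34 and 0.30 without Piezo1 GOF replicates 1 and 3, and the BMP and GDF median was 0.40, 0.46 and 0.44 without WT replicate 2, WT replicate 3 and Piezo1 GOF replicate 2. Without Piezo1 GOF replicate 2 it was 1 for Wnt and 2 for BMP and GDF, and the BMP and GDF count was also 2 without WT replicate 2 and 8 without Piezo1 GOF replicate 3; camera lost that list without WT replicate 3 (adjusted p = 0.053) or Piezo1 GOF replicate 2 (0.0955).

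Of the groups tied directly to mechanical signalling, none passed camera with all 6 libraries, and YAP and TAZ targets passed fry. Of 12 tendon transcription factors, 2 rose and 0 fell, with a median log2 fold change of -0.16 (camera adjusted p = 0.830). Beside Scx, whose value is uncertain because of Bop1, the other was Mohawk (Mkx), from 48.1 ± 6.11 to 118 ± 43.7 CPM (1.29 ± 0.28; edgeR adjusted p = 0.104 over all genes), and 2 of the list rose whichever library was left out, while the median was -0.083 without WT replicate 2 and 1 member fell without WT replicate 1 or Piezo1 GOF replicate 1. Eya1 (-1.03 ± 0.35) did not pass. Of 11 mechanosensitive channels, 3 rose and 0 fell, with a median of 0.34 (camera adjusted p = 0.0515). The 3 were polycystin-2 (Pkd2, 1.22 ± 0.34), Piezo2, from 38.9 ± 14.0 to 76.2 ± 8.89 CPM (0.97 ± 0.28), and Trpv4 (1.09 ± 0.35), and Tmem63b was at -0.70 ± 0.29. This count was 2 without WT replicate 1 or Piezo1 GOF replicate 1, 1 without Piezo1 GOF replicate 3 and 0 without the others, and the list passed without Piezo1 GOF replicate 2 (camera adjusted p = 0.0134). Targets of the mechanically regulated co-activators YAP and TAZ did not pass (19 genes; median -0.10; camera adjusted p = 0.388), although fry gave a lower set (adjusted p = 0.0362). The median was -0.15 and -0.28 without Piezo1 GOF replicates 1 and 3 and -0.06 without WT replicate 1, where 2 members fell. Of these the ecto-nucleotidase Nt5e rose (1.31 ± 0.23), a call lost without WT replicate 3, and the transcription factor Tead1 (-1.03 ± 0.31), Arhgef17 (-0.56 ± 0.22) and Crim1 (-0.54 ± 0.21) did not pass. Calcium and NFAT signalling (camera adjusted p = 0.561), immediate early genes (0.830), actin cytoskeleton and focal adhesion (0.852) and cell proliferation (0.385) did not pass, except proliferation without Piezo1 GOF replicate 2 (0.0157). The median of the immediate early genes was 0.08 while their mean was -0.06 and the test pointed down, and without 1 library the median lay between -0.42 and 0.26. In the calcium list the kinase gene Camk4 rose (1.90 ± 0.43), and in the adhesion list the collagen-binding integrin gene Itga11 rose from 60.4 ± 2.61 to 114 ± 4.57 CPM (0.91 ± 0.18). The Camk4 call was lost without WT replicate 3 or Piezo1 GOF replicates 2 or 3, and that of Itga11 without any 1 WT library or Piezo1 GOF replicates 1 or 3.

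**Figure D3:**
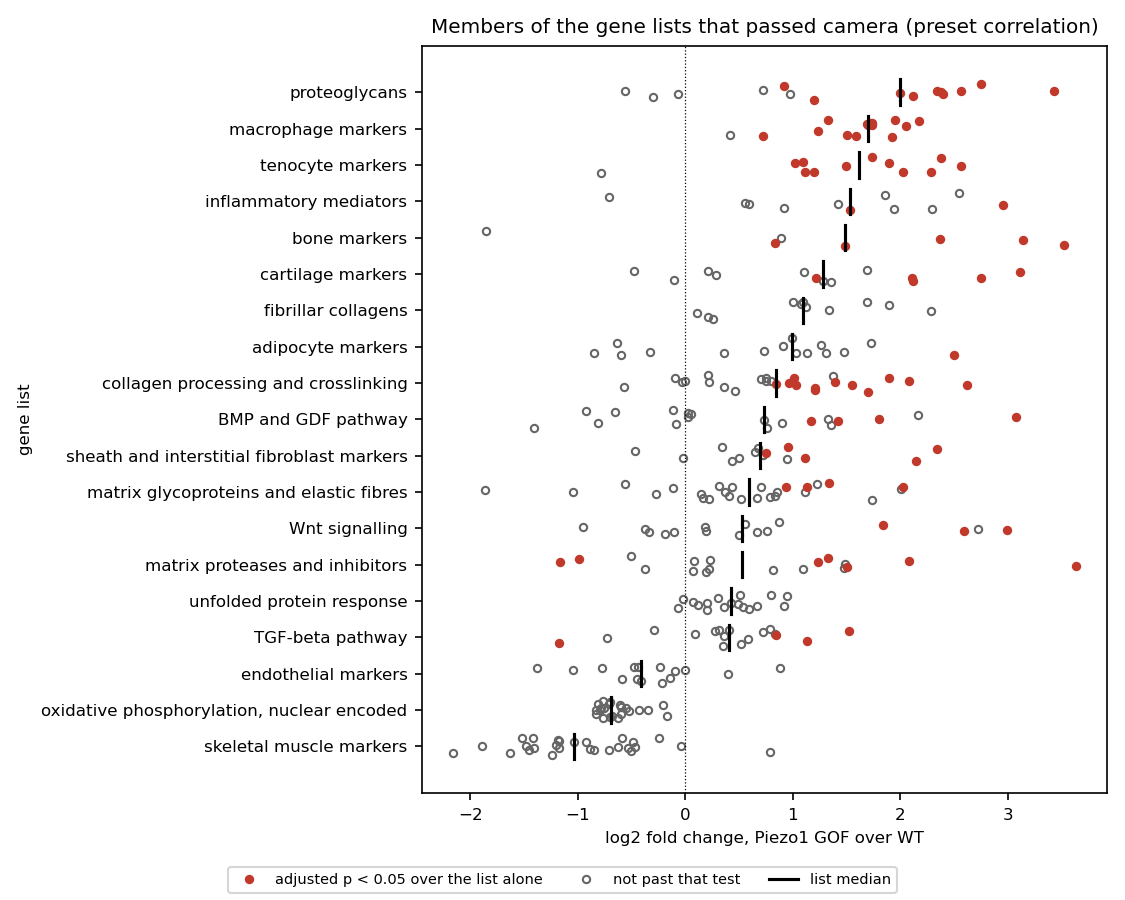
Log2 fold change of Piezo1 GOF over WT (horizontal axis) of each tested member of the 19 lists that passed camera with the preset correlation (vertical axis). Red points passed with the adjustment over the list alone, open points did not, and black lines mark list medians, which run from -1.04 for skeletal muscle markers to 1.99 for proteoglycans.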

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

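The removal of Rn45s and Lars2, the robust prior and the list counts without each library were chosen only after the results were seen. Wif1 and Lyz1, the 2 genes called, were called again with median-ratio or upper-quartile factors, a CPM filter, the muscle and erythroid lists removed, Rn45s and Lars2 removed, and a robust prior, each time as 2 genes. The count was 0 with library size only, which moved the median log2 fold change of all genes from -0.004 to 0.1002, 0 with the muscle score as a covariate, and 0 at an adjusted p under 0.01. It was 151 genes (128 higher, 23 lower) at an adjusted p under 0.1, 165 (141 higher, 24 lower) with no low-count filter, 882 (511 higher, 371 lower) with DESeq2, 689 (452 higher, 237 lower) with edgeR's exact test and 116 (97 higher, 19 lower) with limma voom with quality weights. Leaving out 1 library gave 0 to 228 genes, with 0 to 182 higher and 0 to 46 lower; the highest counts came without WT replicate 1 and 0 without each of the others. The causes were not tested. The log2 fold change of Scx, 1.95 and just short of the threshold, passed it with no low-count filter (1.94), DESeq2 (1.93), the exact test (1.95), voom (1.82) and without WT replicate 1, and ranged from 1.73 to 2.14 over the libraries left out; its adjusted p ranged from 1.002e-07 with DESeq2 to 0.346 with the muscle covariate. Piezo1 passed under none of these. Of 84 genes followed, 0 changed direction under any alternative. Most were picked by a small p in the main fit of the same libraries, so a kept direction is no independent check. DESeq2 took 54 past the threshold, the exact test 46, no filter 24, the fit without WT replicate 1 20 and voom 17.

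The replicate numbers are not said to pair the samples. The deviations of same-numbered libraries from their group means had correlations of -0.21, -0.14 and -0.05, which gave no sign of a pairing. Differences in muscle content and the nerve transcripts of WT replicate 1 could mask one. With the replicate block in the fit, 0 genes were called and 23 lists.

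The count of 19 lists was 0 for camera with an estimated correlation and 2 for fry (macrophage markers and YAP/TAZ targets). It lay between 19 and 24 under the other alternatives in which lists were tested, including 19 to 23 without 1 library. Lists were not tested with DESeq2, the exact test, voom, the robust prior or other thresholds. With the muscle score as a covariate the calls of muscle, endothelial, unfolded protein response and BMP and GDF lists were lost, of which the muscle list is itself the covariate, while erythroid (adjusted p = 0.000892), Schwann cell (0.00259; median -3.75), mechanosensitive channel (0.0267), IGF and FGF (0.0308), interferon (0.0308) and mural lists (0.0317) passed; over the alternatives the lowest and highest adjusted p of these 6 lists lay between 0.000892 and 0.856. Each list that changed direction, named below, had missed the threshold with all 6 libraries and no covariate. Without 1 library the median log2 fold change of tendon transcription factors ranged from -0.22 to -0.083, of immediate early genes from -0.42 to 0.26, of actin cytoskeleton and focal adhesion from -0.30 to 0.32, of cell proliferation from -0.10 to 0.51 and of Schwann cell markers from -3.17 to 1.36. With the muscle score as a covariate the test of tendon transcription factors (median -0.14), immediate early genes (0.53; adjusted p = 0.0105, the lowest of its alternatives, the highest being 0.958) and glycolysis and hypoxia (-0.00892) turned, and with fry that of tendon transcription factors (-0.16) and actin cytoskeleton and focal adhesion (-0.17). The causes were not tested, apart from the nerve transcripts of WT replicate 1 in the Schwann cell list. The muscle covariate leaves 3 residual degrees of freedom and is itself lower in the mutant group, so a call lost there is no measure of a weaker effect. In the simulation with these library sizes, dispersions and 3 libraries per group, 10% of 2-fold changes were recovered. Depth was not varied, and genes were drawn independently, unlike those of the real libraries.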

Other observations

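The fits of marker scores with the muscle score as a covariate were chosen only after the results were seen and the patterns weighed below were noticed in these data, while the predictions of the other tests were written before their values were computed. Over all genes, 70 genes, Scx among them, shared the third smallest adjusted p of 0.0572 and missed the threshold by edgeR's quasi-likelihood test; those named next stand in none of the gene lists and were picked after their values were seen. Higher in all 3 mutant libraries were Retnla, a secreted protein of alternatively activated macrophages (2.80 ± 2.24 CPM in WT, 41.5 ± 21.3 CPM in Piezo1 GOF; log2 fold change 3.90 ± 0.58), and Tnfrsf11b, the decoy receptor osteoprotegerin (9.81 ± 4.19 and 48.8 ± 13.5 CPM; 2.33 ± 0.38). The gap junction gene Gja1 was at 127 ± 44.9 and 639 ± 223 CPM (2.33 ± 0.38), the growth factor Pdgfc at 8.61 ± 1.21 and 31.9 ± 3.32 CPM (1.89 ± 0.22), and the annexin Anxa8 at 50.4 ± 14.1 and 227 ± 17.7 CPM (2.17 ± 0.27). Lower in all 3 mutant libraries were Chrna1, a subunit of the muscle acetylcholine receptor (29.8 ± 5.28 and 7.004 ± 3.38 CPM; -2.11 ± 0.35), the flavin monooxygenase Fmo2 (-2.26 ± 0.36) and Rhobtb3 (-1.52 ± 0.21).

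Tenocyte and macrophage transcripts were higher in the libraries with the lower share of muscle transcripts, where Ttn, the most abundant muscle marker, was at 64031 CPM in WT and 23007 CPM in Piezo1 GOF with overlapping groups; 0 of the 27 muscle and 0 of the 15 macrophage markers stand in another list. Less muscle RNA with all other cell types in unchanged proportion would raise their markers alike, yet the tenocyte score exceeded the endothelial score by 2.07 (SE 0.69) more in Piezo1 GOF than in WT on the log2 scale, and the macrophage score by 1.88 (SE 0.26), which argues against it. Muscle tissue carries its own vessels, so a smaller share of both was examined with the muscle score as a covariate. The macrophage difference went from 1.57 to 1.41 (SE 0.33, 95% interval 0.37 to 2.45) and so stayed above 0 at a given score. That score overlapped between the genotypes (10.11 in WT replicate 1, 10.20 in Piezo1 GOF replicate 1), while the muscle share of counts did not. The fit may therefore adjust too little and cannot decide whether that share is the whole cause. The tenocyte difference went from 1.76 to 0.87 (SE 0.66; 95% interval -1.23 to 2.97), so for tenocyte genes a genotype effect and a smaller share of muscle tissue in the dissected piece cannot be told apart, since the muscle score moves with the genotype and 3 residual degrees of freedom remain. For macrophage genes an effect of the genotype may remain, untested against differences in dissection or in the cell make-up of the tendon.

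Scx was higher in Piezo1 GOF and lies inside Bop1. Reads of Bop1 counted for Scx could raise its value, since Bop1 had a log2 fold change of 3.14 (SE 0.56), above that of Scx. The pair did not keep step across the mutant libraries, however. Scx went from 77.9 CPM in replicate 1 to 60.2 and 45.1 CPM in replicates 2 and 3. Bop1 was far higher in replicate 1 and lower in replicate 2 than in replicate 3, so sharing of reads is not settled. A candidate explanation for the rise of both genes is transcription from the Scx-Cre transgene, if it carries Scx and Bop1 sequence. The other 8 tested genes within 100 kb had a median log2 fold change of -0.20 (SE 0.20) and 0 of them were called. The transgene is present only in the mutant genotype and counts per gene do not separate its transcripts from those of the chromosomal locus, so this remains a hypothesis. Higher transcription of the chromosomal Scx gene stays open and untested.

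Wif1 and Lyz1 both lie on chromosome 10. A uniform shift of the whole segment would move their neighbours as well. The 48 other tested genes within 5 Mb had a median log2 fold change of 0.0455 (SE 0.13). This stood at percentile 69.0 of 10000 random gene sets of that size, which argues against a uniform shift of the segment. Single neighbours ranged from -1.32 to 2.28. A piece of another strain's chromosome could change single genes in either direction, which a median cannot show, so it was not tested.

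Of the 10 splits of the 6 libraries into 3 and 3, 1 gave at least as many genes, the real one with 2, and the highest other gave 1. For lists, 3 of the 10 gave at least as many as the real 19, and the highest other gave 20. At an unadjusted p under 0.05 the real split gave 2664 genes and the highest other 1519. With 10 splits no share under 0.05 can be reached. The other splits hold the genotypes in unequal numbers on each side, so part of a genotype difference can remain in them.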
